A study of Mus musculus with 3 samples.

How the data were processed

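Gene expression was measured in mouse bone marrow-derived dendritic cells, antigen-presenting cells grown from bone marrow progenitors. Per the labels, the marrow came from female mice aged 6 weeks, GM-CSF was given at 20 ng/mL, and nonadherent cells were collected on day 7. The cells were then kept for 24 h with PBS as the control, with LPS (lipopolysaccharide, a bacterial ligand of Toll-like receptor 4) at 1 µg/mL, or with a stimulus labelled PTX at 100 ng/mL. The labels do not spell out PTX, and the abbreviation is kept here. The strain label of the PTX sample reads C57BL/7, and those of the PBS and LPS samples read C57BL/6. Each of the 3 groups held 1 array. The labels do not tell whether the 3 cultures came from 1 mouse or 1 marrow preparation, so a difference between animals or preparations was not separable from one between groups.

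Per the labels, 3 µg of total RNA was converted to biotin-labelled cRNA and hybridized to Affymetrix arrays. The deposited table holds 1 intensity per probe set and array on a linear scale, with a lowest value of 1. The program that summarized the probes, its background correction and its scaling are not given in the sources used here. The median intensity over all 45101 probe sets was 85.7 on the PBS array, 65.3 on the LPS array and 86.9 on the PTX array, so the arrays had not been brought to a common median.

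Intensities were used as deposited, and log2 values were taken after a pseudocount of 16 was added, which shrinks the differences of dim probe sets. A difference is thus on the log2(intensity + 16) scale. Of the probe sets, 64 were controls, 34958 had 1 gene symbol in the platform annotation, 932 had several and 9211 had none listed there. Those with several or none were left out of the gene comparisons, and none of the symbols needed updating through the reference gene table. The table of RefSeq genes used for names belongs to the assembly GRCm38.p6, and no coordinates are given because the sources used here name no build. Each of 18193 genes was represented by its probe set with the highest mean log2 value over the 3 arrays. A gene counted as measured when that probe set reached, on at least 1 array, the median of all values of the noncontrol probe sets, an intensity of 78.9. This left 12299 genes, of which 7392 had several probe sets.

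The comparisons were LPS against PBS, PTX against PBS and PTX against LPS. With 1 array per group there was no replicate check of any difference, no spread within a group could be estimated and no test was possible, so no p-value and no standard deviation or standard error within a group is given and genes are described by the size of the difference. Genes at least 2-fold apart (a log2 difference of at least 1) were counted in each direction. The number of arrays limits the precision of every value.

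Before the data were examined, 36 gene lists were fixed. They covered inflammatory cytokines, chemokines, chemoattractant and prostanoid receptors, costimulation and maturation, MHC class I and class II presentation, type I interferon-stimulated genes, interferon-gamma-inducible GTPases and effectors, the NF-kB pathway, Toll-like receptor signalling, T helper polarising factors, cAMP-responsive genes and G protein signalling. Others covered the cell cycle, glycolysis, oxidative phosphorylation, cholesterol synthesis, cholesterol efflux, endocytic receptors, alternative activation, eicosanoid synthesis, matrix proteases, the unfolded protein response, oxidative stress, cell death, reference genes and dendritic cell subsets. The rest were markers of other cells a culture could hold, namely macrophages, neutrophils, T cells, B cells, NK cells, mast cells with eosinophils, erythroid cells with megakaryocytes, stromal cells and plasmacytoid dendritic cells. Of 663 list symbols, 596 had a probe set (3 under an older name) and 539 were measured. Lists share some members, such as 8 genes held by both the cytokine and the T helper lists.

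For each list the median log2 difference of its measured members was taken, with its percentile among 10000 random lists of the same size matched on mean expression in 20 bins. The percentile describes these arrays and is not a test. A list was called apart when its percentile lay below 2.5 or above 97.5, and lists with fewer than 5 measured members got no percentile. Intervals of list medians are 95% bootstrap intervals over the members (2000 draws) and show the spread between genes, not between samples. The genes named are the 15 with the largest positive and the 15 with the largest negative difference in each comparison, and up to 4 members of each list with the largest differences, plus members that show a list's spread. Predicted genes without an established name were counted and not named, and where 5 or fewer members of a list passed 2-fold they may all be named. Other genes and families are named only where stated, after their values were seen.

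Both stimuli were compared with the same PBS array, so the overlap of their genes was set beside the overlap of independent lists and beside 200 simulations of unchanged arrays against 1 shared control. The noise of these simulations came from the disagreement between probe sets of 1 gene. A difference between cultures that moves all probe sets of a gene alike is not in that noise. The gene and list steps were checked on simulated data. With a noise of 0.25 per array added to 12299 genes, 86% of 50 genes shifted by 1.5 and 98% of 50 shifted by -1.5 were counted as 2-fold apart, as were all those shifted by 3 or -3, and 0.47% of 12099 unshifted genes were counted. On the arrays, the disagreement between probe sets of 1 gene had a standard deviation per difference of 0.70 for LPS against PBS, 0.28 for PTX against PBS and 0.72 for PTX against LPS, so the simulated noise was too small for the comparisons with LPS. Unchanged genes with differences drawn from that disagreement, in 200 simulations chosen after the results were seen, were counted as 2-fold apart in 15.6%, 1.48% and 16.1% of 12299. The 0.47% was thus too low for PTX against PBS as well. There the drawn differences gave a mean of 181.5 genes, and normal noise of the same standard deviation gave 5.17. Of 400 unshifted random lists of 20 genes, 6.5% lay outside the central 95%, and all of 100 lists shifted by 0.5 did. These lists had the noise of 0.25 per array, drawn independently for each gene. The 2 rates need not hold for the gene lists used here, whose members may vary together, or for the larger noise of the comparisons with LPS.

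The alternatives fixed before the data were examined were quantile normalization, median centring, lowess centring (span 0.3), pseudocounts of 64 and 1, no filter on low values, a filter at the 75th percentile of the mean, the mean of all probe sets of a gene, leaving out probe sets that can match several transcripts or genes, the mean of a list in place of its median, and random lists not matched on expression. After the data were seen, scaling to the bacterial hybridization controls and a comparison of PTX with PBS without the LPS array were added. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.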

Results

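The data comprised 3 arrays of mouse dendritic cells, 1 each after PBS, LPS or PTX for 24 h, and the series title sets the LPS response against the PTX response. Across all probe sets, Pearson's r of the log2 values was 0.974 between the PTX and PBS arrays, 0.909 between LPS and PBS, and 0.906 between PTX and LPS. These correlations are across probe sets, which are not independent replicates. The share of probe sets at or above the level for a measured gene was 52.5% on the PBS array, 44.7% on the LPS array and 52.8% on the PTX array.

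The LPS array also stood apart in probe sets that do not measure dendritic cell messenger RNA. The 18 bacterial hybridization controls, added to each sample before hybridization, differed by a median absolute log2 value of 0.20 between LPS and PBS and of 0.04 between PTX and PBS. In LPS against PBS 14 of the 18 lay above 0. The 24 bacterial poly-A controls had a median of 0.26 in LPS against PBS, with all 24 above 0. In PTX against PBS their median was -0.07, with 8 above 0. In both control sets several probe sets read the same added transcript, so these counts are not of independent controls. The 5′ probe set of 18S ribosomal RNA read 6788 on the PBS array, 1514 on the LPS array and 9946 on the PTX array, whereas its 3′ probe set read 1766, 2958 and 1970, so that the ratio of 3′ to 5′ was 0.26, 1.95 and 0.20. The same ratio was 1.33, 1.39 and 1.40 for beta-actin and 1.02, 0.96 and 1.12 for Gapdh. Every statement below that involves LPS rests on this array.

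LPS against PBS addresses which genes differed after a Toll-like receptor 4 ligand. Dendritic cells kept with LPS had higher levels of interferon-stimulated genes, inflammatory cytokines, costimulatory molecules and MHC class I presentation genes, and lower levels of cell cycle genes, than cells kept with PBS. Irf7, a transcription factor of the interferon response, read 6370.2 against 317 (log2 difference 4.26), and Il1b, an inflammatory cytokine, read 11315 against 1770.3 (2.67). Top2a, the DNA topoisomerase of dividing cells, read 162 against 1471 (-3.06). In all, 799 genes were at least 2-fold higher and 1601 at least 2-fold lower, and 40 and 51 were at least 8-fold apart. With noise as large as the disagreement between probe sets of 1 gene, a mean of 1917 unchanged genes would be counted as at least 2-fold apart, against the 2400 seen. That disagreement also holds real differences between transcripts, so this number does not measure noise alone. The disagreement leaves out differences between cultures that move all probe sets of a gene alike, so it gives no full count for unchanged cultures.

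Among the genes with the largest positive differences were Cfb (complement factor B, 5.55), Ly6i (4.95), the scavenger receptor gene Marco (4.52), Saa3 (serum amyloid A 3, 4.33), Ptges (prostaglandin E synthase, 4.28), Irf7 and 3 members of the Ms4a membrane protein family (Ms4a6b 4.67, Ms4a6c 4.43, Ms4a4c 4.19). U90926 (7.33), H2bc22 (6.5), Ctla2b (4.39), Plpp1 (4.22), Kctd14 (4.10) and Lef1 (4.04) made up the rest of the 15. The other measured probe set of Ms4a6c differed by -0.05 (51.1 against 53.5). Among the genes with the largest negative differences were Ccr2, the receptor for Ccl2 on monocytic cells (-5.06, with all 3 of its other measured probe sets at least 2-fold lower too), Mgl2, a C-type lectin of alternatively activated cells (-4.17), Cenpe, a kinetochore motor (-4.38), and Asgr2 (-4.68). Pdgfd (-6.16), Cabp7 (-5.37), Pak3 (-5.01) and Arhgap20os (-4.42) were bright on the PBS array alone, and Rpl39 (-5.63), Opcml (-4.84), Gli2 (-4.00), Zbtb7a (-3.97), Mrpl33 (-3.97), Vpreb3 (-3.85) and Mamdc2 (-3.81) completed the list. Of these, all from Rpl39 on except Vpreb3 were low on the LPS array alone, with Rpl39 at 4933 (PBS), 83.9 (LPS) and 4709 (PTX). They belong to the 29 genes for which failing single probe sets are weighed below. Cenpe and Gli2 each had 1 other measured probe set, which was also at least 2-fold lower, whereas none of the other measured probe sets of Cabp7 (1) and Zbtb7a (2) was. With a pseudocount of 1 Cabp7 was represented by another probe set, and its difference was then 0.048. The lower of the 2 readings was under the measured level for 12 of the 15 lower and 5 of the 15 higher genes, so the sizes and order of these differences depend on the pseudocount. Pdgfd, for example, was at -4.48 with a pseudocount of 64 and at -8.02 with a pseudocount of 1.

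Type I interferon-stimulated genes, the antiviral effectors and sensors downstream of the interferon receptor, had a median log2 difference of 2.24 in LPS against PBS (95% bootstrap interval over members 1.57 to 2.51, percentile 100). Of 25 measured members 22 were at least 2-fold higher, led by Irf7, Ifit3 (3.57), Zbp1 (3.57) and Oasl2 (3.24), and 3 were within 2-fold (Irf9 0.36, Trim30a 0.22, Mx1 0.14). Of 15 interferon-gamma-inducible genes 11 were higher and 4 within 2-fold (median 1.28, percentile 100), with Gbp6 at 3.74, Socs1 at 2.84 and Nos2, the inducible nitric oxide synthase, at 2.06. Of 16 MHC class I presentation genes 11 were higher and 5 within 2-fold (median 1.23, percentile 100), led by the immunoproteasome subunits Psmb9 (1.78) and Psmb8 (1.64). Of 13 MHC class II genes 11 were within 2-fold and 2 lower (H2-DMa -1.09, H2-Ob -1.04), with a median of 0.27 (percentile 72.6).

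Of 18 inflammatory cytokines 12 were at least 2-fold higher in LPS, 1 was lower and 5 were within 2-fold (median 1.27, interval 0.71 to 1.82, percentile 100). Il1b, Il12b (2.44), Il6 (2.36) and Il12a (2.26) led the list, and Csf1, the macrophage growth factor, was lower (-1.33). Of 22 chemokines 10 were higher, 1 was lower and 11 were within 2-fold (median 0.69, percentile 100). Cxcl5 (3.72), Xcl1 (2.83), Ccl5 (2.29) and Ccl2 (2.22) were the highest, Cxcl11 was lower (-1.80) and Cxcl10 differed by 0.36. Of 20 NF-kB pathway genes 8 were higher and 12 within 2-fold (median 0.62, percentile 99.99), with the feedback inhibitor Socs3 at 2.85 and Traf1 at 2.15. The T helper polarising list, which shares 8 members with the cytokines, had a median of 1.05 with 9 of 16 higher, none lower and 7 within 2-fold (percentile 100), and outside the shared members Itgb8 had the largest difference (2.71).

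Costimulation and maturation genes had a median of 1.05 in LPS against PBS (interval 0.57 to 1.63, percentile 100), with 14 of 24 higher, 9 within 2-fold and 1 lower. The cytokine receptor chains Il15ra (2.16) and Il2ra (2.09) and the costimulatory receptor Cd40 (1.97) were highest, and the endocytic receptor gene Ly75 was lower (-2.71). Among 19 chemoattractant and prostanoid receptors 4 were higher (Fpr2 1.57, Ccrl2 1.41, the lymph node homing receptor Ccr7 1.39, Cxcr4 1.30), 4 were lower (Ccr2, Cx3cr1 -1.73, Ackr3 -1.44, Ccr6 -1.01) and 11 were within 2-fold. Their median was -0.30 (percentile 1.35, back inside the central 95% in 7 of 12 alternatives), and it turned to 0.024 with median centring and to 0.22 with the filter at the 75th percentile. Of 16 alternative activation genes 6 were lower, 2 higher and 8 within 2-fold (median -0.43, percentile 0.55, and 2.62 with random lists not matched on expression), with Mgl2, Clec10a (-2.80) and Klf4 (-2.47) low and Socs1 high.

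Cell cycle genes had a median of -1.54 in LPS against PBS (interval -2.18 to -1.26, percentile 0). Of 29 measured members 24 were at least 2-fold lower and 5 within 2-fold, with Cenpe, the mitotic cyclin gene Ccnb2 (-3.39), the anaphase activator gene Cdc20 (-3.12) and Top2a lowest and the replication clamp gene Pcna at -0.11. Metabolic lists differed less. Of 17 glycolysis genes 3 were higher (Pfkfb3 2.58, Pfkl 2.10, Slc16a3 1.09) and 14 within 2-fold, with a median of 0.61 (percentile 99.7), and the 24 oxidative phosphorylation genes had a median of 0.51 (percentile 98.6) with 1 higher (Sdhb 1.04) and 23 within 2-fold. The latter percentile fell inside the central 95% in 4 of 12 alternatives. Of 17 oxidative stress genes 2 were higher (Mt2 1.5, Sod2 1.47), 3 lower (Gclm -1.37, Gclc -1.10, Nqo1 -1.04) and 12 within 2-fold, with a median of 0.52 (percentile 98.2) that was also lost in 4 of 12 alternatives. Toll-like receptor signalling genes had a median of 0.25 (1 of 21 higher, 1 lower, percentile 96.7, apart in 3 of 12 alternatives) and endocytic receptors of 0.08 (percentile 21.1, with a sign that differed between scalings). Of 12 eicosanoid synthesis genes Ptges and Ptgs2 (1.60) were higher, Alox5 was lower (-1.25) and 9 were within 2-fold (median 0.36, percentile 98.2, lost in 5 of 12 alternatives).

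The direction of the smaller differences from LPS depended on the scaling. Of the genes at least 2-fold apart in LPS against PBS 33.3% were higher with the values as deposited, 45.6% (989 higher, 1182 lower) with quantile normalization and 58.1% (1449 higher, 1045 lower) with median centring. The median of all measured genes was -0.08 as deposited, 0.11 with quantile normalization and 0.27 with median centring. Relative to that median, over 5 scalings, the interferon-stimulated list lay between 1.96 and 2.32, the cytokine list between 1.33 and 1.43 and the cell cycle list between -1.49 and -1.43. Of 272 higher genes with another measured probe set 134 (49.3%) had one that was at least 2-fold higher too, and of 584 lower genes 266 (45.5%) had one at least 2-fold lower.

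PTX against PBS addresses which genes differed after PTX. Cells kept with PTX had higher levels of interferon-stimulated genes, of some macrophage markers and of several Toll-like receptor genes, and lower levels of cell cycle and some cholesterol synthesis genes, than cells kept with PBS, while most inflammatory cytokines were at or below the PBS level. Most macrophage markers and most cholesterol synthesis genes were within 2-fold. Ifit3, an interferon-induced antiviral effector, read 3648 against 203 (log2 difference 4.07), Irf7 read 5399 against 317 (4.02), and Birc5, the mitotic gene for survivin, read 163 against 961 (-2.45). At least 2-fold differences were seen in 374 higher and 292 lower genes, and 33 and 8 were at least 8-fold apart, where noise of that kind would give 181.5 unchanged genes at 2-fold.

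The genes with the largest positive differences in PTX against PBS were Ms4a6c (5.27), Ms4a6b (5.22), the interferon-inducible gene Ifi213 (5.09), Unc13a (4.75), Spata7 (4.49), Plac8 (4.38), Dbx1 (4.20), Ifit3, Irf7, Ms4a4c (3.97), Cfb (3.96), Fcgr4 (an Fc receptor for IgG, 3.90), Ifit2 (3.62), Ifit1bl1 (3.60) and Sema3c (3.55). The other measured probe set of Sema3c lay in the opposite direction (-1.34, 29.3 against 98.4), and that of Ms4a6c differed by 0.61. Unc13a, Spata7 and Dbx1 were above the measured level on the PTX array alone. Each had 1 probe set, so no other probe set could check them. The genes with the largest negative differences included Car4 (carbonic anhydrase 4, -3.82), Plet1 (-3.71), Ear3 (an eosinophil-associated ribonuclease, -3.61), Hspa1a (inducible heat shock protein 70, -3.15), Ccl17 (a chemokine of dendritic cells, -2.73), the spindle gene Nusap1 (-2.74) and the mitotic ubiquitin conjugase gene Ube2c (-2.62). Pdgfd (-5.88), Cabp7 (-5.44), Pak3 (-5.12) and Arhgap20os (-3.74), which were bright on the PBS array alone, and Hoxa11os (-2.79), Dnal1 (-2.79), Kif27 (-2.76) and Mrpl38 (-2.69, not 2-fold lower in its other measured probe set) were the others. Hoxa11os and Kif27 were above the measured level on the PBS array alone too, and Dnal1 read 860 (PBS), 102 (LPS) and 111 (PTX). Of the 2 other measured probe sets of Plet1, 1 was at least 2-fold lower too (-2.19). Plet1 differed by 0.058 when probe sets that can match several transcripts were left out, and Cabp7 by 0.30 with a pseudocount of 1. The lower reading was under the measured level for 6 of the 15 higher and 8 of the 15 lower genes, whose order depends on the pseudocount as well.

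Type I interferon-stimulated genes had a median of 2.45 in PTX against PBS (interval 2.27 to 2.58, percentile 100). Of 25 members 24 were at least 2-fold higher, led by Ifit3, Irf7, Ifit2 and Zbp1 (3.16), and Irf9 was within 2-fold (0.95). Of 15 interferon-gamma-inducible genes 11 were higher (median 1.34, percentile 100), including the GTPase genes Gbp6 (3.49), Iigp1 (3.40), Ifi47 (2.20) and Irgm2 (2.05). The 4 within 2-fold were Cxcl9 (0.76), Socs1 (0.18), Ido1 (0.14) and Nos2 (-0.07). Of 16 MHC class I genes 5 were higher (Nlrc5, the class I transactivator, 2.17, Tap1 2.07, Psmb9 1.45, H2-M3 1.34, Tapbp 1.13) and 11 within 2-fold, with a median of 0.83 (percentile 100). MHC class II genes had a median of 0.18 (percentile 92.2), with Lgmn higher (1.36), H2-Ob lower (-2.07) and 11 of 13 within 2-fold.

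Of 18 inflammatory cytokines 3 were at least 2-fold higher in PTX (Il12b 2.52, Il18 1.29, Il15 1.17), 3 were lower (Il6 -1.57, Il1a -1.40, Tnf -1.28) and 12 were within 2-fold, with Il1b at 0.06. The median was -0.17 (interval -0.70 to 0.11) and its percentile of 2.06 passed inside the central 95% in 4 of 13 alternatives. Of 22 chemokines 17 were within 2-fold (median -0.07, percentile 7.08, apart in 2 of 13 alternatives). Those lower were Ccl17, the neutrophil attractants Cxcl1 (-2.41) and Cxcl2 (-2.12), and Ccl24 (-1.09), and Ccl5 was higher (1.62). Of 20 NF-kB pathway genes 19 were within 2-fold and Socs3 was higher (1.27), with a median of -0.03 (percentile 24.8) that was 0.30 and apart (percentile 99.0) when probe sets that can match several transcripts were left out. The T helper list had 2 higher, 1 lower and 13 within 2-fold (median 0.05, percentile 69.9, with a sign that differed between scalings). Of 24 costimulation and maturation genes 3 were higher (Il15ra 1.23, Cd83 1.2, Serpinb9 1.18) and 21 within 2-fold, with Cd86 at 0.72, Cd40 at 0.66 and Cd80 at 0.08 (median 0.33, percentile 99.98).

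**Figure D1:**
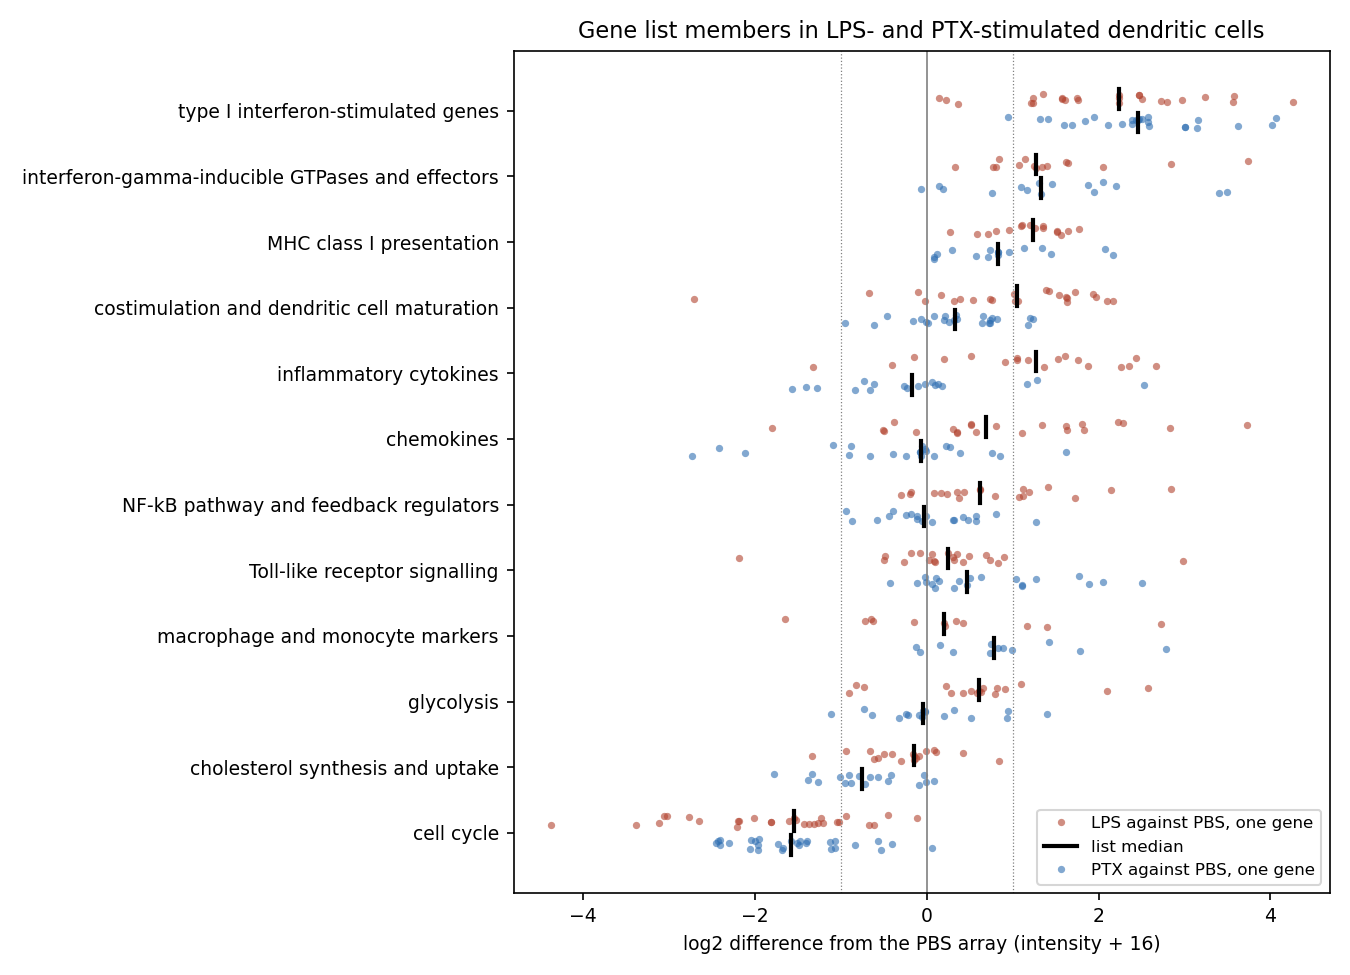
Log2 differences from the PBS array of the measured members of 12 gene lists, where each point is 1 gene on 1 array (red LPS, blue PTX), scattered vertically only for legibility, black bars are list medians and dotted lines mark 2-fold. The interferon-stimulated list has medians of 2.24 in LPS and 2.45 in PTX, and the inflammatory cytokine list has medians of 1.27 and -0.17.

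Toll-like receptor signalling genes had a median of 0.47 in PTX against PBS (percentile 100). Of 21 members 8 were higher and 13 within 2-fold, led by Tlr1 (2.5), Tlr3, the sensor of double-stranded RNA (2.05), and the paired genes Cd180 (1.89) and Ly86 (1.78), with Tlr4 at 0.09 and Cd14 at -0.02. Macrophage and monocyte markers had a median of 0.79 (percentile 100), with Fcgr1 (2.79), Mertk (1.78) and Maf (1.42) higher, 9 of 12 within 2-fold and the complement gene C1qc at 0.99, against a median of 0.21 (percentile 45.7, with a sign that differed between scalings) in LPS. Chemoattractant receptors had a median of 0.62 (percentile 100), with Cxcr4 (1.35), C3ar1 (1.34) and Ccrl2 (1.09) higher, Hcar2 lower (-1.75) and 15 of 19 within 2-fold. Endocytic receptors had a median of 0.31 (percentile 99.8), with 4 of 23 higher, 2 lower and 17 within 2-fold. The Fc receptor genes Fcgr4 and Fcgr1 and the clearance receptor gene Mertk were among the higher ones and Mgl2 (-2.14) was lowest.

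Cell cycle genes had a median of -1.58 in PTX against PBS (interval -1.97 to -1.39, percentile 0), with 24 of 29 at least 2-fold lower and 5 within 2-fold. Birc5, the ribonucleotide reductase gene Rrm2 (-2.43), Top2a (-2.41) and Bub1 (-2.41) were lowest, and Tyms differed by 0.07. Cholesterol synthesis genes had a median of -0.75 (percentile 0), with 5 of 18 lower (Fdps -1.78, Hsd17b7 -1.38, Sqle -1.34, Cyp51 -1.26, Idi1 -1.01) and 13 within 2-fold, against a median of -0.15 (percentile 29.0, positive with median centring) in LPS. Of 18 cholesterol efflux and lipid handling genes 4 were higher in PTX (Apoe 2.11, Apoc2 1.84, Fabp4 1.59, Abca1 1.10) and 14 within 2-fold (median 0.35, percentile 99.9), against a median of 0.17 in LPS (percentile 49.3, with a sign that differed between scalings). Of 17 oxidative stress genes 4 were lower (Nqo1 -2.29, Gclm -1.65, Gclc -1.24, Hmox1 -1.08) and 13 within 2-fold (median -0.58, percentile 0). Of 16 alternative activation genes 6 were lower, among them Ccl17, Retnla (-2.15), Mgl2 and Klf4 (-1.31), and 10 were within 2-fold (median -0.29, percentile 0.08). Medians of oxidative phosphorylation and glycolysis genes were -0.06 (percentile 4.73) and -0.05 (percentile 14.5), and that of eicosanoid synthesis genes was -0.01 (percentile 40.0).

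No scaling moved the split of this comparison by 10 percentage points, the filter at the 75th percentile gave 66.8% higher (276 higher, 137 lower) against 56.2%, and without the LPS array, an alternative chosen after seeing the data, 374 genes were higher and 294 lower, of which 368 and 284 were shared with the counts above. Of 151 higher genes with another measured probe set 99 (65.6%) had one at least 2-fold higher too, and of 127 lower genes 76 (59.8%) had one at least 2-fold lower.

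PTX against LPS sets the 2 stimuli side by side. The median of the interferon-stimulated genes was higher with PTX, and those of cytokines, chemokines, NF-kB regulators and maturation genes were lower, with most members of the interferon, NF-kB and maturation lists within 2-fold. Il6 read 181 with PTX and 2974 with LPS (log2 difference -3.92), Ptgs2, the inducible cyclooxygenase gene, read 37.5 and 889 (-4.08), and Cxcl1 read 366 and 7223 (-4.24), while Ccr2 read 4448 and 71.7 (5.67). At least 2-fold differences were seen in 1681 higher and 767 lower genes, a total of 2448, where noise of that kind would give 1976.

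Of 25 interferon-stimulated genes 20 were within 2-fold between PTX and LPS and 5 were higher with PTX (Ifit2 2.05, Trim30a 1.37, Stat2 1.34, Cmpk2 1.17, Mx1 1.17), with a median of 0.45 (percentile 99.93, 0.11 to 0.56 over 5 scalings). Interferon-gamma-inducible genes had a median of 0.03 (percentile 45, with a sign that differed between scalings). Socs1 (-2.66), Nos2 (-2.12) and Ido1 (-1.13) were lower with PTX, Iigp1 (2.64), Irgm1 (1.11) and Gbp8 (1.01) were higher, and 9 were within 2-fold. Of 18 cytokines 12 were lower with PTX, 2 were higher (Il15 1.31, Il18 1.09) and 4 within 2-fold (median -1.52, interval -1.96 to -0.53, percentile 0). Il12b, which encodes the p40 chain of interleukin 12, differed by 0.09, and Il12a, which encodes the p35 chain, by -2.12. Of 22 chemokines 11 were lower, 1 was higher (Cxcl11 1.72) and 10 within 2-fold (median -1.04, percentile 0), with Cxcl1, Cxcl5 (-3.80) and Ccl17 (-3.54) lowest.

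Of 20 NF-kB pathway genes 8 were lower with PTX than with LPS and 12 within 2-fold (median -0.81, percentile 0), with the feedback regulator Tnfaip3 at -2.0 and Tnip1 at -1.63. Of 24 maturation genes 6 were lower, 17 within 2-fold and 1 higher (Ly75 3.47), with a median of -0.75 (percentile 0). MHC class I genes were all within 2-fold (16 members, median -0.37, percentile 5.61, apart in 1 of 12 alternatives). Cell cycle genes had a median of 0.20 (percentile 73.5), with 25 of 29 within 2-fold and 4 higher with PTX (Cenpe 2.33, Cdc20 1.64, Ccnb2 1.33, Bub1b 1.29), and the median turned negative with quantile normalization and median centring. Macrophage markers had a median of 0.72 (interval -0.26 to 1.57, percentile 99.99), with 6 of 12 higher, 6 within 2-fold and C1qc at 1.71, and 5 members lay below 0. With the filter at the 75th percentile this median was 0.061 and no longer apart (percentile 89.8).

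Several metabolic lists were lower with PTX than with LPS. Medians were -0.66 for glycolysis (4 of 17 lower, 13 within 2-fold, percentile 0.04, lost in 1 of 12 alternatives), -0.55 for oxidative phosphorylation (1 of 24 lower, 23 within 2-fold, percentile 0.14), -0.54 for cholesterol synthesis (2 of 18 lower, 16 within 2-fold, percentile 0.06) and -0.58 for oxidative stress (5 of 17 lower, 12 within 2-fold, percentile 0.33, lost in 1 of 12). Their sizes depended on the scaling. Relative to the median of all measured genes, over 5 scalings, glycolysis lay between -0.76 and -0.24 and oxidative phosphorylation between -0.64 and -0.20. Cholesterol synthesis lay between -0.64 and -0.53 and oxidative stress between -0.68 and -0.31. The T helper list was at -1.01 (8 of 16 lower, 1 higher, 7 within 2-fold, percentile 0), mast cell and eosinophil markers at -1.38 (3 of 6 lower, 3 within 2-fold, percentile 0.01) and neutrophil markers at -0.63 (3 of 10 lower, 1 higher, 6 within 2-fold, percentile 0.28, lost in 1 of 12). Eicosanoid synthesis genes had a median of -0.37 (2 of 12 lower, 1 higher, 9 within 2-fold, percentile 1.67, lost in 5 of 12). Cholesterol efflux genes were at 0.39 (5 of 18 higher, 13 within 2-fold, percentile 99.9, lost in 1 of 12), and endocytic receptors at 0.17 (8 of 23 higher, 3 lower, 12 within 2-fold, percentile 97.7, lost in 3 of 12, with a sign that differed between scalings).

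The other lists with a percentile were not apart in PTX against LPS. Medians were 0.23 for chemoattractant receptors (percentile 91.8, apart in 3 of 12 alternatives), 0.29 for Toll-like receptor genes (percentile 94.4, apart in 2 of 12) and -0.34 for reference genes (percentile 13.5, apart in 1 of 12). They were 0.07 for G protein signalling, 0.09 for cAMP-responsive genes, 0.02 for matrix proteases, -0.10 for the unfolded protein response, -0.07 for cell death, 0.14 for alternative activation and -0.04 for MHC class II genes. Plasmacytoid and subset dendritic cell markers were at 0.22 and -0.12, erythroid markers at -0.12 and stromal markers at 0.03. Among all these, only the reference and subset lists kept the sign of their median over 5 scalings. Of the T cell, B cell and NK cell lists, without a percentile, the medians were 0.36, 0.92 and 0.25, the last with a sign that differed between scalings.

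**Figure D2:**
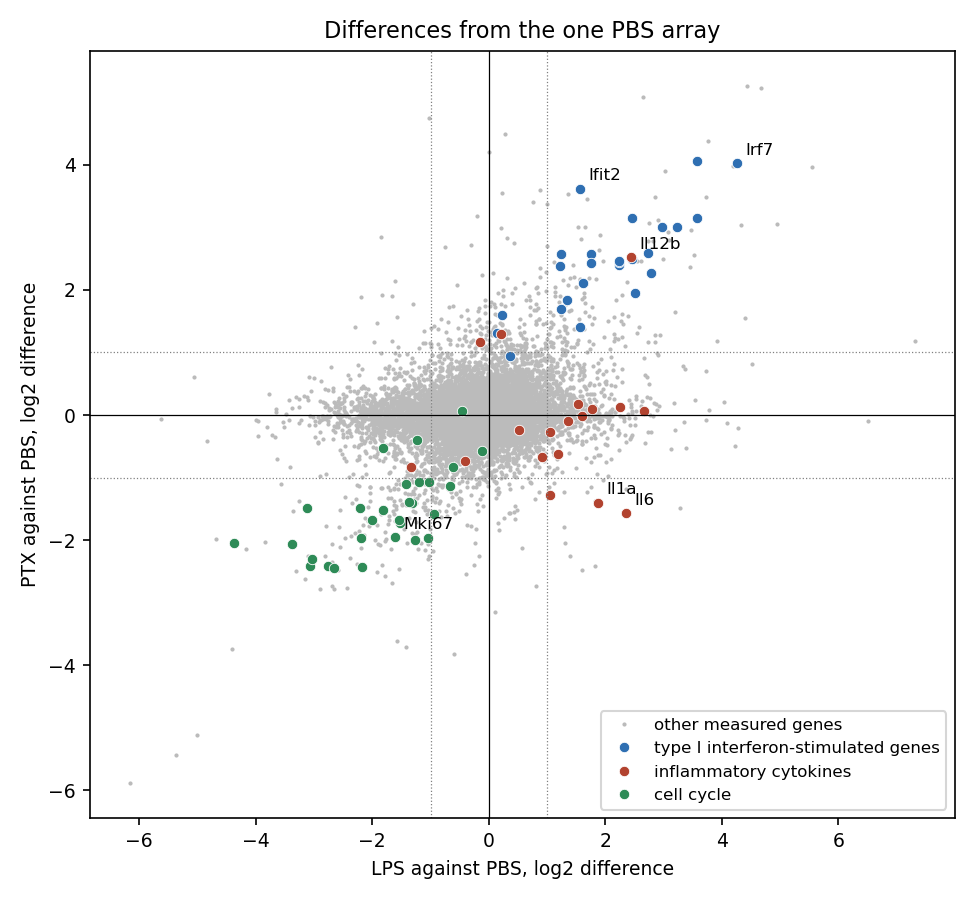
Log2 difference from the PBS array in LPS (horizontal) and in PTX (vertical) for 12299 measured genes, 1 point per gene, with 3 gene lists coloured, dotted lines at 2-fold and the same PBS array behind both axes. Interferon-stimulated genes lie to the upper right, most cytokines lie to the right near or below 0 in PTX (Il6 at 2.36 and -1.57), and cell cycle genes lie to the lower left.

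Besides Cxcl1, Ptgs2, Il6 and Cxcl5, given above, the 15 genes with the largest negative differences in PTX against LPS were H2bc22 (-6.59), U90926 (-6.15), Prg2 (eosinophil major basic protein, -4.77), Plpp1 (-4.72), Ptges (-4.49), Kctd14 (-4.23), Itm2a (-3.91), Lef1 (-3.83), Marco (-3.71), Rprm (-3.70) and Adgb (-3.68). Those with the largest positive differences besides Ccr2 were Unc13a (5.77), Rpl39 (5.56), Nppa (4.71), Opcml (4.44), Spata7 (4.21), Dbx1 (4.20), Macroh2a3 (4.10), Cd180 (4.08), Gli2 (3.91), Zbtb7a (3.87), Arhgap15 (3.75), Gzmk (3.74), Map3k12 (3.74) and Apoc1 (3.71). None of the 2 other measured probe sets each of Zbtb7a and Map3k12 was 2-fold higher. Rpl39, Opcml, Macroh2a3, Gli2, Zbtb7a, Map3k12 and Apoc1 were low on the LPS array alone and within 2-fold in PTX against PBS. Unc13a, Spata7 and Dbx1, with 1 probe set each, were above the measured level on the PTX array alone. The lower reading was under the measured level for 12 of the 15 higher and 9 of the 15 lower genes, so that Opcml, for example, was at 2.97 with a pseudocount of 64 and at 5.84 with a pseudocount of 1. The higher share of the genes apart was 68.7% as deposited, 53.2% (1224 higher, 1077 lower) with quantile normalization and 40.5% (1070 higher, 1575 lower) with median centring. The median of all measured genes moved from 0.09 to -0.14 and -0.28.

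**Figure D3:**
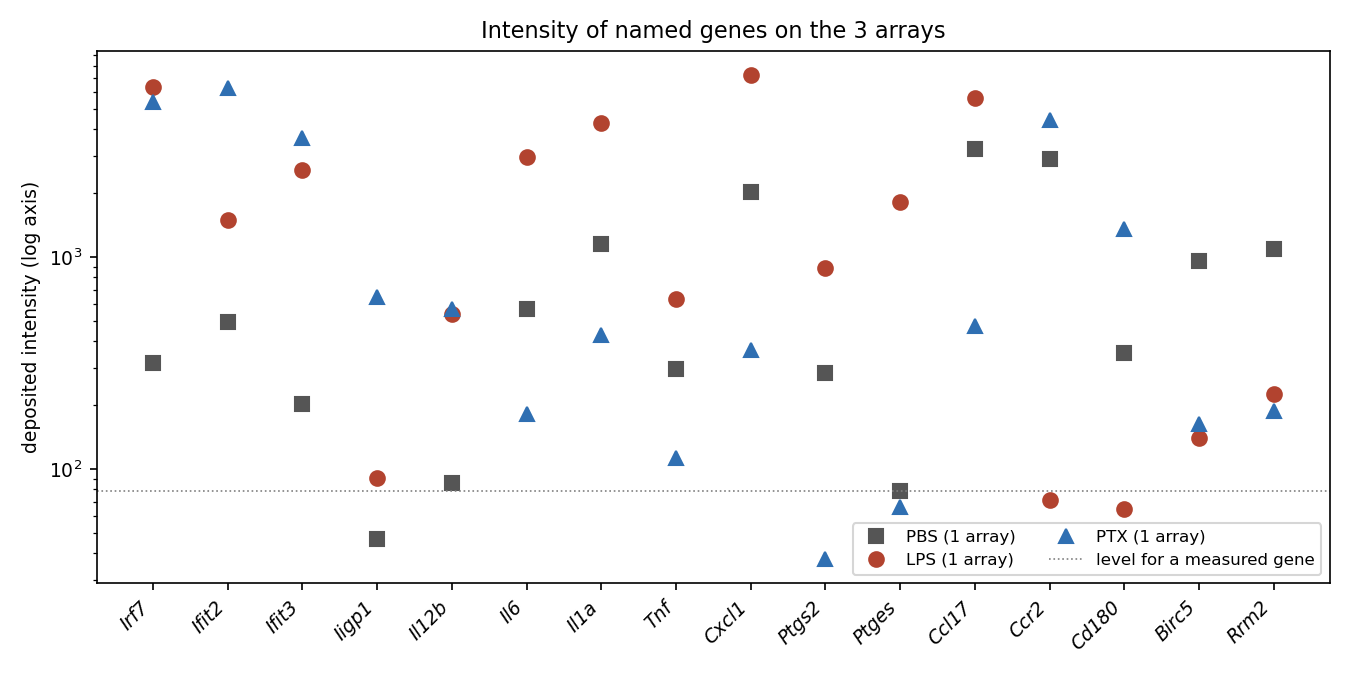
Deposited intensity (log axis) of 16 named genes on the 3 arrays, 1 symbol per array, with a dotted line at the level for a measured gene (78.9). Irf7 and Ifit3 are high with LPS and with PTX, Il6, Cxcl1 and Ptgs2 are highest with LPS and lowest with PTX, and Birc5 and Rrm2 are highest with PBS.

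Of the genes at least 2-fold higher than in PBS, 159 were higher with both stimuli, among 799 for LPS and 374 for PTX. Independent lists of these sizes would share 24.3, and unchanged arrays against 1 shared control gave a mean of 30.3 (17 to 49). Of the lower genes 167 were lower with both, against 38.0 for independent lists and 30.5 (18 to 46) for unchanged arrays. Opposite differences were seen in 17 genes higher with LPS and lower with PTX (19.0 for independent lists, 1.27 for unchanged arrays) and in 18 genes lower with LPS and higher with PTX (48.7 and 1.24). Part of the excess of shared directions may come from the shared PBS array. The simulations cannot show how much, because their noise leaves out a PBS culture departing alike in all probe sets of a gene. Unchanged arrays also give fewer genes to share. Noise of that kind gave a mean of 181.5 genes at 2-fold in PTX against PBS, where 666 were seen. The simulated counts are thus not those of lists of the observed sizes, and shares in common were not compared.

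Markers of other cells differed in both directions. The T cell, B cell and NK cell lists had only 4, 4 and 3 measured members and got no percentile, with medians of -0.47, -0.51 and 0.30 in LPS (the NK cell value turned negative under some scalings) and -0.18, 0.05 and 0.66 in PTX against PBS. Mast cell and eosinophil markers had a median of 1.47 in LPS (percentile 100), with Prg2 (3.28), Cpa3 (2.33) and Hdc (2.12) higher, Siglecf lower (-2.15) and 2 of 6 within 2-fold, and of -0.12 in PTX (percentile 19.2, apart in 1 of 11 alternatives). Neutrophil markers had medians of 0.14 (percentile 71.6, -0.0049 to 0.46 over 5 scalings) and -0.25 (percentile 0.34, inside the central 95% in 3 of 13 alternatives, with a median as near 0 as -0.024), the latter with an interval of -0.69 to 0.58 and with 2 of 10 members higher, 1 lower and 7 within 2-fold. In LPS 2 were higher, 2 lower and 6 within 2-fold, with Lcn2 higher in LPS (3.91) and in PTX (1.18), and S100a9 at -1.0 and -1.82. Medians in LPS and PTX were 0.17 and -0.07 for erythroid and megakaryocyte markers, -0.05 and -0.02 for stromal markers (Dcn 2.78 in LPS), -0.05 and 0.23 for plasmacytoid dendritic cell markers (Bst2 3.45 and 2.37), and 0.30 and -0.01 for dendritic cell subset markers (Cd24a -0.16 and -2.25, Flt3 1.33 and 1.78). None of these 4 lists was apart in either comparison as deposited, the plasmacytoid list in PTX was in 6 of 12 alternatives and the subset list in LPS in 3 of 12, and the signs of the LPS medians of the first 3 differed between scalings.

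The remaining lists had small medians. In LPS and PTX against PBS these were -0.11 and 0.06 for cAMP-responsive genes (Fosb -1.24 and -1.87, Pde3b -1.98 and 0.27), -0.13 and 0.05 for G protein signalling genes (Rgs18 -1.38 and -1.26), 0.12 and 0.12 for matrix proteases (Mmp19 -2.69 and -2.06), 0.02 and -0.07 for the unfolded protein response, and 0.36 and 0.12 for cell death genes. The signs of the LPS medians of the first 4, and of the PTX median of the G protein list, differed between scalings. Of these 5 lists only the cell death list, in LPS, was apart as deposited (percentile 97.8, lost in 3 of 12 alternatives, with 3 of 19 higher, 3 lower and 13 within 2-fold), and in PTX the cell death and the cAMP list were each apart in 2 of 13 alternatives. Reference genes had medians of 0.27 (percentile 53.9) and -0.06 (percentile 11.2), and the LPS value ranged from -0.10 to 0.59 over 5 scalings.

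Members of several lists that were apart went in both directions, and the bootstrap interval of the median then held 0. In LPS against PBS this was so for chemoattractant receptors, alternative activation, eicosanoid synthesis, oxidative stress, cell death and mast cell lists. In PTX against PBS it was so for cytokines, cholesterol efflux, oxidative stress and neutrophil lists, and in PTX against LPS for endocytic receptors, eicosanoid synthesis, macrophage, neutrophil and mast cell lists.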

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

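The tests of explanations in this part (hybridization controls, the count after quantile normalization, unnamed probe sets against named ones, probe sets of the same gene, the share of the LPS excess, list medians in proportion, the highest cell cycle median and the PTX against LPS median) were chosen only after the results were seen. Of 3624 measured probe sets without a gene name here, which no comparison above used, 128 were at least 2-fold higher and 1203 lower in LPS than on the PBS control array, and 105 were higher and 40 lower in PTX. The largest positive differences were 5.47 for 1 probe set in LPS (3336 against 59.4) and 5.50 for another in PTX (2139 against 31.7, and 479.7 in LPS). The 5′ control probe set of 18S ribosomal RNA was 0.55 above PBS on the PTX array. These items stand here because they carry signal above the control array outside the gene comparisons. A probe set without a name is one for which the annotation used here lists no gene, so it may still read a known gene.

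The LPS array stood apart, with 2400 genes at least 2-fold from PBS against 666 for PTX, and with 36.7% of unnamed probe sets at least 2-fold apart against 4.0% for PTX. Array scaling as the whole cause is argued against by quantile normalization, after which LPS still had 3.04 times as many such genes as PTX. Array handling or hybridization remains open. The hybridization controls, which hold no mouse RNA, were spread 7.18 times as widely between LPS and PBS as between PTX and PBS. This was after the median offset that an overall scaling factor would give was removed. An earlier form that kept the offset gave 5.31 and was replaced after its result was seen. The bootstrap interval of the 7.18 (1.98 to 44.2) is over the 18 control probe sets. Several of these read the same added transcript, so they are not independent and the interval may be too narrow. A smaller share of RNA outside named genes in the LPS sample cannot be told apart from array handling. The lower unnamed probe sets (-0.37 against named ones of the same PTX-array level, interval -0.41 to -0.33) prompted that explanation. They only lack a gene in the annotation used here, so they may read known genes. The 5′ and 3′ probe sets of 18S ribosomal RNA went opposite ways in LPS against PBS (-2.15 and 0.74). Single probe sets failing on the LPS array cannot be told apart either, for the 29 genes at least 8-fold lower there than on both other arrays. Only 11 had another measured probe set, of which 45.5% (exact 95% interval 16.7% to 76.6%) were at least 2-fold lower too. A response of the cells to LPS, the biological difference in the design, was not separable with 1 array.

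Interferon-stimulated genes were higher in PTX without most of the inflammatory cytokines. RNA or cells of the LPS culture in the PTX sample are argued against by the 29 cytokine, chemokine and NF-kB genes at least 2-fold higher in LPS, of which a median of -0.76% of the LPS excess over PBS was present in PTX (interval -10.9% to 2.73%), while 22 interferon-stimulated genes had 121% (95.8% to 167%). Cxcl9, which the chemokine list shares with the interferon-gamma list, was left out of the 29. An earlier form of this test on all genes higher in PTX, which also argued against it, was replaced after its result was seen. An LPS-like stimulus acting on all lists in proportion would put the 59 measured members of the cytokine, chemokine and NF-kB lists, again without Cxcl9, at a median of 1.00 in PTX. The observed median was -0.075 (interval -0.24 to -0.0087). This median and the share of the LPS excess both come from the lists that defined the pattern. They set the pattern beside each explanation and are not evidence separate from it. An LPS-like response with another time course or dose response for each list, such as one to a trace of LPS, was not tested, and a response to PTX itself that includes interferon signalling is a candidate explanation that these arrays leave open.

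Cell cycle genes were lower in LPS and in PTX than in PBS. Array scaling is argued against, since the highest list median over 5 scalings and both comparisons was -1.22. The single PBS array departing from its group, for example a culture with more dividing cells, cannot be told apart from a shared response to both stimuli, because the list differed by only 0.20 between PTX and LPS (interval -0.14 to 0.36) and both comparisons use that array. Less proliferation after either stimulus may account for the pattern as well and was not tested further.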

How the results depend on the processing

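The scaling to hybridization controls and the comparison without the LPS array were chosen after the data were seen, and the other alternatives before. Of the list medians recomputed under alternatives 1049 stayed within the bootstrap interval of the value from the primary analysis, 44 moved beyond it, and 3 more, of lists that were apart, turned direction. In all 103 of these 1096 medians changed sign, since 92 of the 1049 and 8 of the 44 did so too. Of the percentiles 1124 stayed on their side of the limits, 44 passed inside the central 95% and 27 passed outside it. Of the values of named genes 754 moved by less than the disagreement between probe sets, 115 by more, and 3 turned direction. Some marker lists had too few members for a value under some alternatives. The medians of interferon-stimulated genes (both stimuli), cytokines in LPS and cell cycle genes (both stimuli) kept their direction and their place outside the central 95% under every alternative tried. The causes were not tested, except that stricter filters and larger pseudocounts leave fewer genes or shrink dim ones by construction. No paired analysis was possible because each group had 1 array. How far signal over background limits the dim genes was not measured. The level for a measured gene is the median of all values over the 3 arrays, and 44.7% of probe sets on the LPS array reached it.

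With median centring, counts were 1449 higher and 1045 lower (LPS against PBS) and 1070 higher and 1575 lower (PTX against LPS), and 11 genes were lower with LPS and higher with PTX. List medians in LPS against PBS were 0.024 (chemoattractant receptors, opposite in sign), 0.60 (MHC class II), 1.55 (MHC class I), 2.56 (interferon-stimulated), 0.57 (Toll-like receptors), -1.22 (cell cycle), 0.93 (glycolysis), 0.83 (oxidative phosphorylation), 0.17 (cholesterol synthesis, opposite in sign), 0.85 (oxidative stress), 0.68 (cell death) and 0.59 (reference). In PTX against LPS they were -0.17 (endocytic receptors), -0.11 (chemoattractant receptors), -1.06 (maturation), -0.71 (MHC class I), -0.31 (interferon-gamma), -0.33 (G protein), -0.14 (cell cycle), -1.0 (glycolysis), -0.89 (oxidative phosphorylation), -0.88 (cholesterol synthesis), -0.71 (eicosanoid), -0.44 (unfolded protein), -0.41 (cell death) and -0.68 (reference), of which the endocytic, chemoattractant, interferon-gamma, G protein and cell cycle values were opposite in sign to those as deposited.

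With quantile normalization, medians were 0.95 (MHC class I), 0.18 (oxidative phosphorylation) and -0.081 (reference, opposite in sign) in LPS against PBS, -0.17 (oxidative phosphorylation) and -0.15 (reference) in PTX against PBS, and -0.10 (MHC class I), -0.17 (cell cycle, opposite in sign) and -0.018 (reference) in PTX against LPS. With lowess centring they were 0.21 (oxidative phosphorylation) and -0.10 (reference, opposite in sign) in LPS against PBS, and -0.10 (MHC class I), -0.32 (oxidative phosphorylation) and -0.0091 (reference) in PTX against LPS.

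With a pseudocount of 64, 1019 genes were lower in LPS against PBS and 1101 higher in PTX against LPS, 11 were higher with LPS and lower with PTX, 10 were lower with LPS and higher with PTX, and the cell cycle median in PTX was -1.29. With a pseudocount of 1 the last overlap was 28, and Cabp7, represented by another probe set, was at 0.048 in LPS and 0.30 in PTX. With the filter at the 75th percentile, counts were 447 higher and 497 lower (LPS against PBS), 137 lower (PTX against PBS) and 612 higher and 408 lower (PTX against LPS), overlaps were 62 lower in both and 11 higher with LPS and lower with PTX, and the chemoattractant receptor median in LPS was 0.22 (opposite in sign).

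With the mean of all probe sets, medians were -1.24 and -1.34 (cell cycle in LPS and PTX) and -0.40 (NF-kB, PTX against LPS). Without probe sets that can match several transcripts they were -0.19 (glycolysis, PTX against LPS) and 0.65 (oxidative phosphorylation in LPS), and Plet1 was at 0.058 in PTX. With the mean of the members the eicosanoid value in PTX against LPS was -0.73.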

Other observations

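The families and genes in this part were chosen after their values were seen, so an extreme percentile of a family adds no support. Of 9 measured Ms4a genes, which encode 4-pass membrane proteins, 8 were at least 2-fold higher in LPS (median log2 difference 3.47, 3.23 to 3.82 over 5 scalings) and 6 in PTX (2.56, 2.53 to 2.83), both at percentile 100. Ms4a7 (3.53 and 2.56) and Ms4a6d (3.47 and 2.95) were higher with both, whereas Ms4a8a was at 2.71 in LPS and 0.29 in PTX. Of 7 Schlafen genes 5 were higher in each comparison (medians 1.57 and 2.40, both at percentile 100), and Slfn5 was 1.77 higher in PTX than in LPS. Of 7 genes of the HIN-200 family, which includes sensors of cytosolic DNA, 3 were higher in LPS and 4 within 2-fold, with a median of 0.31 inside the central 95% (percentile 86.9). In PTX 5 were higher (median 1.96, percentile 100), and the median of PTX against LPS was 1.13 (percentile 99.9, 0.79 to 1.23 over 5 scalings). Ifi204 (0.31 and 2.19) and Ifi207 (0.01 and 1.13) were higher in PTX alone, and Aim2 differed by 0.03 and -0.04.

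Genes with opposite differences included, besides Cxcl1, Il6, Il1a, Tnf and Ptgs2, the pentraxin gene Ptx3 (1.31 in LPS, -2.04 in PTX), the C-type lectin gene Clec4e (1.13 and -1.09), Gpr84 (1.83 and -1.37), Phlda1 (1.39 and -2.25) and the long noncoding RNA gene Morrbid (1.29 and -1.23). In the other direction were Ifitm6 (-2.29 and 1.41), Eif2ak2, which encodes the RNA-activated kinase PKR (-1.97 and 1.16), Sp110 (-1.66 and 1.90), Pld4 (-1.91 and 1.47) and Cyp27a1, a sterol hydroxylase gene (-1.30 and 1.78). Neither of the 2 other measured probe sets of Eif2ak2 was 2-fold lower in LPS and 1 was 2-fold higher in PTX, and the other measured probe set of Sp110 was 2-fold higher in PTX and not 2-fold lower in LPS. That of Clec4e was 2-fold lower in PTX and not 2-fold higher in LPS, and that of Ptgs2 was 2-fold higher in LPS and not 2-fold lower in PTX. Of 76 mitochondrial ribosomal protein genes 64 lay above 0 in LPS against PBS (median 0.35, percentile 100, 0.21 to 0.67 over 5 scalings) and 58 lay below 0 in PTX against PBS (median -0.14, percentile 0, -0.20 to -0.14). Most were within 2-fold, 67 in LPS (7 higher, 2 lower) and 74 in PTX (2 lower).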
